A study of Mus musculus with 35 samples.

How the data were processed

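Expression was measured in 35 mouse lung tumour samples on Affymetrix arrays, 1 array per sample. Per the labels, tumours were macrodissected and frozen, RNA was taken out with Trizol and RNeasy, and biotinylated cRNA was made from 10 ug of RNA. The authors deposited a table of intensity values made from the array scans by RMA, as their processing notes state, with no version stated. The deposited values ran from 13.3 to 29170.5, so they were read as intensity on a linear scale and put on the log2 scale. The table held 22690 probe sets, 64 of them array controls. Every column was matched to a sample by its identifier.

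Gene symbols came from the gene table held with the data. Of the probe sets, 20380 had 1 symbol, 691 had several and were left out, and 1555 had no row in that table and were left out. For each gene the probe set with the highest mean over the 35 arrays was used, which gave 12393 genes, of which 4956 had more than 1 probe set. Kras, Nedd9 and Ptk2 had no probe set of their own in this table and were not analysed here. No genome coordinates are given. The 25th percentile of an array lay between 46.2 and 65.5 and the 75th between 302 and 419, and no count-based depth exists for such data, so the spread between arrays sets the precision.

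Samples were grouped from the labels as K primary (9), KL primary (9) and KL metastasis (17, of which 8 in lymph nodes and 9 at distant sites). The part of a sample code shared by a primary tumour and its metastases is called its stem. The labels do not say in words that a stem is 1 mouse. Arrays of 1 stem were checked to deviate together, and the numbers in the sample titles were checked in the same way.

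The comparisons were KL against K primaries with no covariate, KL metastases against KL primaries with stem as a fixed block, KL metastases averaged per stem against K primaries, and lymph node against distant metastases with stem as a fixed block. Each was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Counts are also given at an absolute log2 difference of at least 1. Where 2 KL primaries shared the stem L592, they entered the first comparison as separate arrays.

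The 36 gene lists (18 of pathways, 18 of cell types, 605 members, 529 of them measured) were written from general knowledge. Camera of limma tested each list with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and lists with fewer than 5 measured members would not have been tested. Camera with an estimated correlation and fry were the alternatives. The score of a list in an array is the mean of its members after each gene was centred on its mean over the 35 arrays. Of the fibroblast list, Col1a1, Col1a2 and Col3a1 are also on the matrix list.

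Genes were named by a rule. Stk11 came first in every comparison. In the first pair of comparisons the rule took the 10 largest rises and 10 largest falls past the threshold, with at least 7 of 9 KL primaries on that side of the K median, or the same direction in at least 6 of 8 stems. In the others it took the 5 largest of each, and of each list described up to 4 members with the smallest p. Hmga2, Lox, Vegfc, Cd24a, Src and Nkx2-1 were always given. Genes with only a provisional name were passed over. A list was described when it passed, or when it bore on the study question (epithelial, mesenchymal, Src and focal adhesion, metastasis-associated, LKB1 pathway). The groups, comparisons, tests, lists, naming rule and a first set of alternatives were chosen before the data were examined.

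The alternatives covered a repeated quantile normalization, median centring of each array, leaving out the dimmest 30% of genes, other choices of probe set, every probe set on its own, other variance models, array weights, marker scores as covariates, other treatments of the stem, subsets of the metastases, and leaving out each array or stem. Code range as a block or subset, the 3' to 5' difference as a covariate, leaving out the 4 metastasis arrays that stood apart, leaving out each metastasis array, and averaging KL metastasis 10 and 12 were added after the data were seen. Sample codes below and above 600 were treated as a possible batch because the 3' to 5' difference of K primaries split along them.

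A mast cell list and a list of imprinted growth genes were added after Mcpt1, Mcpt8, Dlk1 and Plagl1 were seen, and their results are under the other observations. The procedure was tested on simulated data with the same designs. Noise was drawn independently for each gene and array, so the recovery values do not cover variation that genes share in the real arrays. At a log2 difference of 1 it recovered 91.2% of changed genes for KL against K primaries, 97.5% for metastases against KL primaries, 77.5% for metastases against K primaries and 80% for lymph node against distant metastases, with 4.23%, 4.71%, 7.32% and 2.67% false calls.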

Results

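Gene expression was measured on 35 arrays of mouse lung adenocarcinoma, each of a different tumour piece. K tumours carried LSL-Kras, an oncogenic Kras allele that Cre recombinase switches on. KL tumours carried the same allele together with floxed Lkb1, the tumour suppressor kinase gene now named Stk11, which Cre removes. Cre was given by adenovirus at 5 to 6 weeks of age. The arrays held 9 K primary tumours, 9 KL primary tumours and 17 metastases of KL tumours, of which 8 were in lymph nodes, 5 in the rib cage, 3 outside the thoracic cavity and 1 in the adrenal gland. The 26 KL arrays fell into 8 sample code stems, each with at least 1 primary tumour and 1 metastasis, and 2 primary tumours shared the stem L592. Deposited intensities ran from 13.3 to 29170.5, with a 75th percentile of 302 to 419 in an array. The number of arrays sets the precision of every value here.

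RNA quality differed between pieces. The mean log2 difference between the 3' and 5' control probe sets of Gapdh and actin was 0.47 ± 0.27 (SD, n = 9) in K primaries and 0.47 ± 0.38 (n = 9) in KL primaries. It was 0.27 ± 0.09 (n = 8) in lymph node metastases and 0.77 ± 0.61 (n = 9) in distant ones. The 4 metastases above 1 were KL metastasis 6, 7, 8 and 16, at 1.49, 1.47, 1.44 and 1.22. Among K primaries it lay between 0.48 and 0.92 in the 5 arrays with sample code numbers below 600 and between 0.17 and 0.27 in the 4 above 600. Code range, RNA quality and genotype were therefore partly mixed, and values within each range are given beside the genotype comparisons.

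Stk11 itself had a mean log2 intensity of 8.45 ± 0.44 (SD, n = 9) in K primaries. It was 7.53 ± 0.24 (n = 9) in KL primaries, 7.54 ± 0.40 (n = 8) in lymph node metastases and 7.33 ± 0.32 (n = 9) in distant metastases. The array labelled KL metastasis 1 stood at 8.47, inside the K range of 7.63 to 8.82 and above every other KL array, of which the highest was 7.94. Its Slc2a3, the gene with the largest fall in KL primaries, was 4.91, below every other array. Its intensities were also the most compressed of the 35 arrays, with a 25th percentile of 65.5 and a 75th of 302. Among K primaries Stk11 was lower where the 3' to 5' difference was larger (r = -0.80, exact permutation p = 0.00649, n = 9). With that difference as a covariate Stk11 was still past the threshold in KL against K primaries (-0.92). A second Stk11 probe set had means of 6.69, 6.57 and 6.67 in K primaries, KL primaries and metastases and did not pass the test in any comparison. In the array labelled KL metastasis 1 it was 7.67, above every K primary. Kras has no probe set named in the gene table and was not analysed here.

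The first comparison set KL primaries, which lost Lkb1, against K primaries. Stk11 fell by 0.92 ± 0.16 (log2, SE, 9 against 9 arrays) in KL primaries, and several of the 10 largest rises were in genes of gastric mucosa, beside Mcpt1, a mast cell protease (35.9-fold). Dmbt1, a mucosal scavenger glycoprotein, rose 52.0-fold (log2 5.70 ± 0.62), from a mean of 6.38 in K to 12.08 in KL primaries. Gkn1, a secreted protein of the stomach lining, rose 25.1-fold (4.65 ± 0.71). Anxa10, an annexin of gastric epithelium, rose 23.9-fold (4.58 ± 0.65). The trefoil factors Tff2 and Tff1, peptides that accompany mucins, rose 12.5-fold and 10.1-fold. Slc2a3, a high-affinity glucose transporter, fell by 4.62 ± 0.39, from 10.80 to 6.19, a 24.5-fold difference.

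Of 12393 genes, 1333 passed in limma, 746 higher and 587 lower in KL primaries, and 353 of these differed by a log2 of at least 1 (263 higher, 90 lower). The rest of the 10 largest rises were Msln, the mesothelial surface protein mesothelin (11.9-fold), and Plac8 (10.1-fold). Prap1 (9.94-fold) and Muc5b, an airway mucin (8.45-fold), completed them. The rest of the 10 largest falls were Ddc, a decarboxylase of monoamine synthesis (log2 -2.81), Apoc1, an apolipoprotein (-2.80), Rbp4, the carrier of retinol (-2.79), and H2-Eb1, an MHC class II chain (-2.69). They also held Plagl1, an imprinted transcription factor gene (-2.55), Pf4, a platelet chemokine (-2.31), Bex4 (-2.29), Ces1d, a carboxylesterase (-2.09), and Cltrn, a membrane protein also called collectrin (-2.07). All 9 KL primaries lay above the K median for each of these rises and below it for each of these falls, and the adjusted p values ran from 9.51e-07 to 0.00612. Of the other genes fixed beforehand, Hmga2, a chromatin protein of fetal tissue, rose by 2.42 ± 0.45 (adjusted p = 0.00172), Lox, which crosslinks collagen, by 1.91 ± 0.29 (0.000263) and Vegfc, a lymphatic growth factor, by 1.07 ± 0.24 (0.00754). Cd24a, a surface glycoprotein (0.76, adjusted p = 0.0665), Src, a tyrosine kinase (0.29, 0.317), and Nkx2-1, the lung lineage transcription factor (-0.75, 0.272), did not pass.

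**Figure D1:**
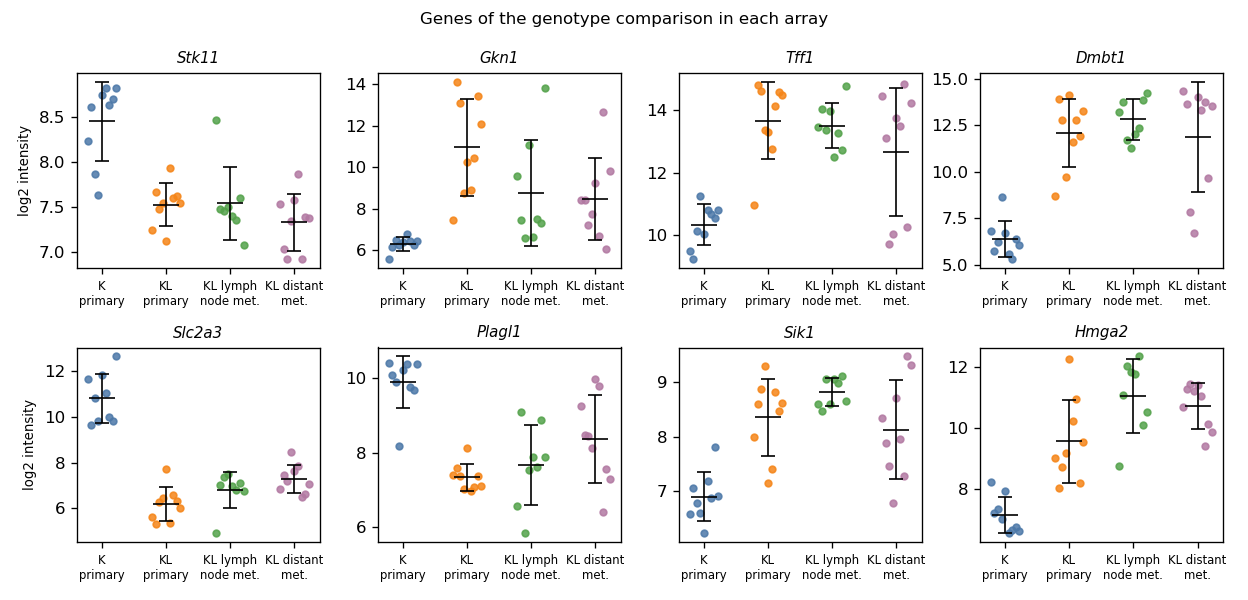
Log2 intensity (y axis) of 8 genes in every array, by group (x axis), with the group mean and SD as bars. Stk11 falls from a mean of 8.45 in K to 7.53 in KL primaries, with the array labelled KL metastasis 1 at 8.47, Dmbt1 rises from 6.38 to 12.08, and Slc2a3 falls from 10.80 to 6.19.

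Gene lists fixed beforehand placed these genes in groups. Targets of CREB and its coactivators CRTC, which the LKB1-dependent SIK kinases restrain, were higher in KL primaries: 7 of 14 measured members rose, 0 fell and 7 did not pass, with 7 past the threshold adjusted over the list alone (median 0.59, camera adjusted p = 0.000137). This was the only 1 of the 36 lists to hold here with an estimated correlation (adjusted p = 0.0204). Its members Sik1, a SIK kinase, rose by 1.46 ± 0.26, Pde4b, a cAMP phosphodiesterase, by 1.15 ± 0.24, Fos by 1.37 ± 0.30 and Dusp1 by 0.99 ± 0.23. The gastric and gut list had 7 of 17 members higher, 0 lower and 10 not past, again 7 when adjusted over the list alone (mean 1.48, median 0.42, adjusted p = 1.96e-05), led by Dmbt1, Tff1, Gkn1 and Tff2. That call was lost with an estimated correlation (adjusted p = 0.241). Members of the LKB1 pathway list itself moved apart: Sik1 and Mark4, a kinase that LKB1 activates (0.65), rose, Stk11 fell and 13 of 16 did not pass, 3 called also when adjusted over the list alone (camera adjusted p = 0.0598). Both other Mark4 probe sets did not pass.

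Some matrix genes were higher in KL primaries, with some stromal markers. Of 22 measured collagen and matrix genes 10 rose, 0 fell and 12 did not pass, with 13 higher when adjusted over the list alone (median 0.68, adjusted p = 8.46e-09). Among them were Loxl1, a collagen crosslinking enzyme (2.22 ± 0.24), and Col3a1, a fibrillar collagen (2.36 ± 0.41). With an estimated correlation the adjusted p was 0.166. Mesenchymal transition genes had 7 of 21 higher, 0 lower and 14 not past, 8 higher when adjusted over the list alone (median 0.42, adjusted p = 1.96e-05, and 0.175 with an estimated correlation). They held Tgfbi, a secreted matrix protein (2.15 ± 0.27), Mmp2, a gelatinase (1.95), and Fn1, fibronectin (1.30 ± 0.24). Fibroblast markers moved in the same direction, with 6 of 16 higher, 1 lower and 9 not past, 10 and 1 when adjusted over the list alone (median 0.76, adjusted p = 1.96e-05, 0.175 with an estimated correlation). Pdgfra (1.95) and Pdgfrb (1.26), receptors of stromal cells, were among the higher. Endothelial markers had 5 of 16 higher and 11 not past, 5 when adjusted over the list alone (median 0.38, adjusted p = 0.00027, 0.241 with an estimated correlation), Sox17 (2.24) among them. Mesothelial markers had 4 of 8 higher and 4 not past, 4 when adjusted over the list alone (median 0.81, adjusted p = 0.00485, 0.0699 with an estimated correlation). Those were led by Msln and Cpe, a carboxypeptidase (2.51).

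A few epithelial genes were higher as well. Of 24 junction and keratin genes 4 were higher, 0 lower and 20 not past, with 7 higher when adjusted over the list alone (median 0.36, adjusted p = 8.32e-05, 0.241 with an estimated correlation). They included Krt19, a simple-epithelium keratin (1.51 ± 0.34), and Dsp, a desmosome protein (1.38 ± 0.24). Src and focal adhesion genes had 4 of 21 higher and 17 not past, 4 when adjusted over the list alone (median 0.37, adjusted p = 1.96e-05, 0.0699 with an estimated correlation). Examples were Itgb4, a laminin receptor chain (1.71 ± 0.35), and Ptk2b, a focal adhesion kinase relative (0.87 ± 0.13). Metastasis-associated genes of other tumours had 5 of 19 higher, 1 lower and 13 not past, 7 and 1 when adjusted over the list alone (median 0.22, adjusted p = 0.00906, 0.0699 with an estimated correlation). Members that rose were Hmga2, Vegfc, Angptl4, a lipase inhibitor (1.03 ± 0.17), and Plaur, the urokinase receptor (0.92 ± 0.22). The cell cycle list was lower (median -0.31, adjusted p = 0.0068, 0.736 with an estimated correlation) with 0 of 23 members higher, 1 lower, also when adjusted over the list alone, and 22 not past. That member was Bub1b, a spindle checkpoint kinase (-0.57 ± 0.15). The cell cycle call was lost without K primary 1 (adjusted p = 0.0863) and with code range as a block (-0.18, adjusted p = 0.229), and its median was 0.09 above code 600.

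**Figure D2:**
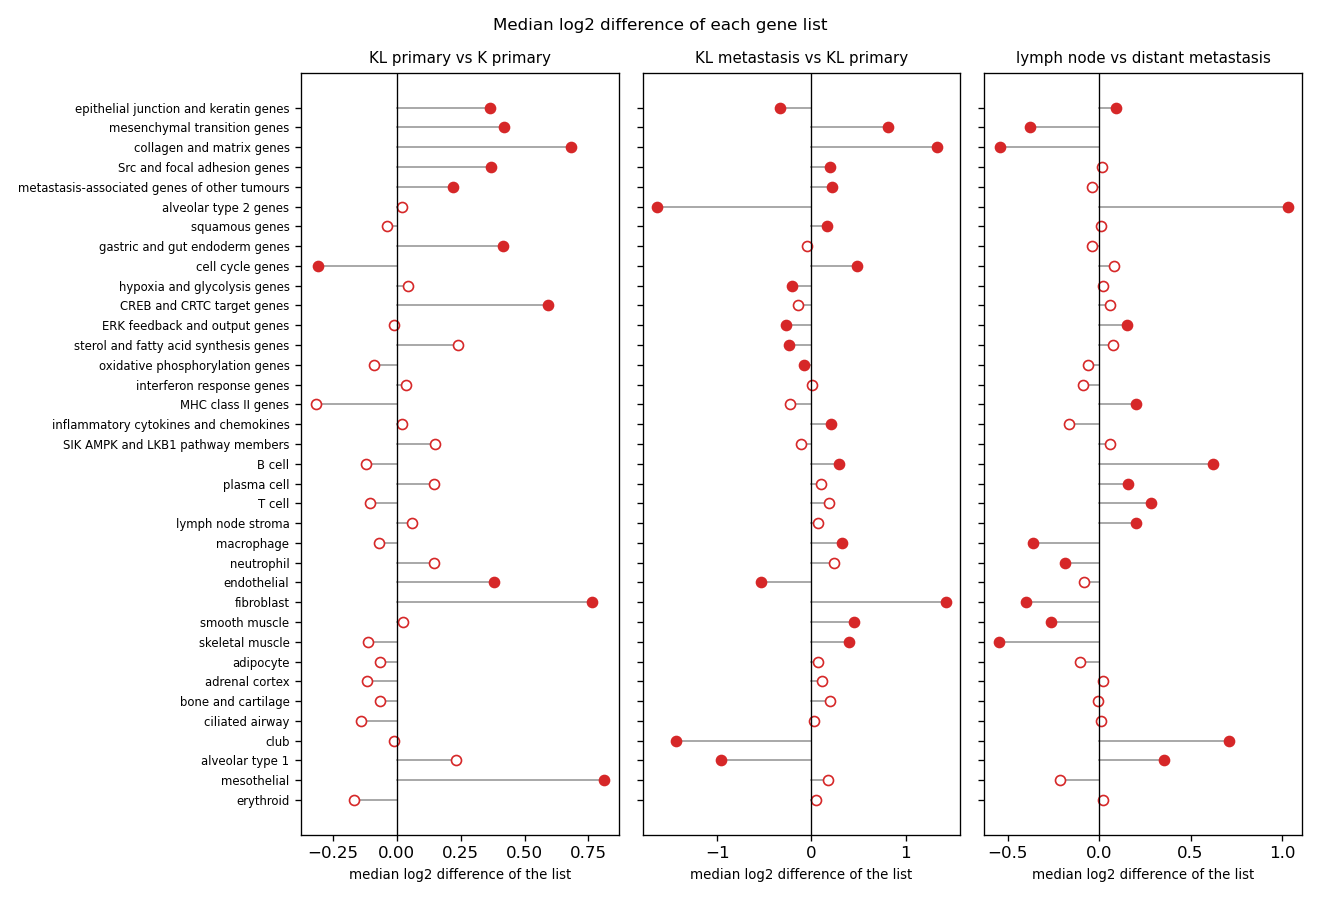
Median log2 difference (x axis) of each of the 36 gene lists (y axis) in 3 comparisons. Filled points passed camera with the preset correlation and open points did not: 11 lists passed for KL against K primaries, 21 for metastases against KL primaries and 17 for lymph node against distant metastases.

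With code range as a block 2285 genes passed (1260 higher, 1025 lower), 3823 passed among the 4 K and 7 KL primaries above 600, and 142 among the 5 K and 2 KL primaries below it. Those 2 share the stem L592, and KL primary 5 of them had a 3' to 5' difference of 1.41, so the values below 600 rest on 1 KL stem. Stk11 was -1.02 with the block, -1.21 above 600 and -0.69 below it, where it did not pass (adjusted p = 0.457). Dmbt1 was 6.03 in all 3 settings, Gkn1 4.35, 4.87 and 3.43, Slc2a3 -4.57, -4.79 and -4.2, and Hmga2 2.89, 2.44 and 3.68. The CREB and CRTC median was 0.53, 0.72 and 0.41, the matrix median 0.65, 0.44 and 1.25, the gastric median 0.67, 1.31 and 0.79, and the fibroblast median 1.01, 1.0 and 1.09, all past the threshold. The epithelial median was 0.24, 0.34 and 0.04 (adjusted p = 0.535 below 600), the endothelial 0.40, 0.65 and 0.04 (0.663 below 600), the mesothelial 0.73, 0.96 and 0.38 (0.114 below 600), and the metastasis-associated 0.41, 0.20 (0.164 above 600) and 0.51. Nkx2-1 was -1.32 with the block (adjusted p = 0.00134) and -1.78 above 600 (0.000219), and Cd24a 0.86 (0.0349) and 1.27 (0.0041), so both passed there. H2-Eb1 was -2.17 with the block and -4.37 below 600, and -0.93 above 600, where it did not pass (adjusted p = 0.0973). Among the genes named in this comparison, the 1 other probe set of Angptl4, Cpe and Pdgfra and 1 of the others of Slc2a3, Lox and Dsp did not pass. The labels give no mouse strain for either genotype, so differences such as that of H2-Eb1 cannot be assigned to Lkb1 loss rather than to strain background.

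The next comparison set the 17 KL metastases against the 9 KL primaries, with code stem as a block, to find what differs between spread tumours and the primaries of the same stems. Stk11 differed by -0.09 ± 0.13 (log2, SE, adjusted p = 0.672). Matrix and stromal genes were higher in metastases: Thbs2, a matricellular thrombospondin, rose 8.15-fold (3.03 ± 0.39, 26 arrays) and was higher in 8 of 8 stems, Mmp13, a collagenase, rose 7.99-fold (log2 SE 0.48) and Tnc, tenascin-C, 6.21-fold (2.63 ± 0.54). Genes of normal lung were lower, with Scgb1a1, the secretoglobin of club cells, 23.0-fold lower (-4.52 ± 0.66) and Inmt, a lung methyltransferase, 13.6-fold lower (-3.77 ± 0.24), each in 8 of 8 stems. The largest fall was in Dlk1, an imprinted Notch pathway ligand gene, 47.2-fold lower with stem as a block (-5.56 ± 0.42), with unblocked group means of 13.18 and 7.87.

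In limma 1719 genes passed, 764 higher and 955 lower in metastases, and 341 of these differed by a log2 of at least 1 (156 higher, 185 lower). Metastases of the same stem counted as separate replicates in this fit, and fewer genes passed with pairs of stem means. The other large rises were Car3, a carbonic anhydrase of muscle and fat (3.18), Moxd1 (2.63), Fbn2, a fibrillin (2.54), Lum, a collagen-binding proteoglycan (2.53), Sfrp2, a secreted Wnt-binding protein (2.5), Fap, the serine protease of activated fibroblasts (2.40), and Serpinf1, a secreted serpin (2.40). The other large falls were Sftpa1, a surfactant protein (-3.58), Itih4 (-3.44), Fmo2, a lung monooxygenase (-3.44), Chil1, a chitinase-like protein (-3.33), Dmkn (-3.33), Cbr2, a carbonyl reductase of club cells (-3.26), and Fbp1, an enzyme of gluconeogenesis (-3.13). These 20 genes had adjusted p values from 1.08e-08 to 0.0271. Hmga2 rose by a further 1.47 ± 0.31 (adjusted p = 0.00352), while Lox (0.62, 0.257), Nkx2-1 (-0.76, 0.108), Vegfc (0.09, 0.809), Src (0.03, 0.864) and Cd24a (0.00, 0.996) did not pass.

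**Figure D3:**
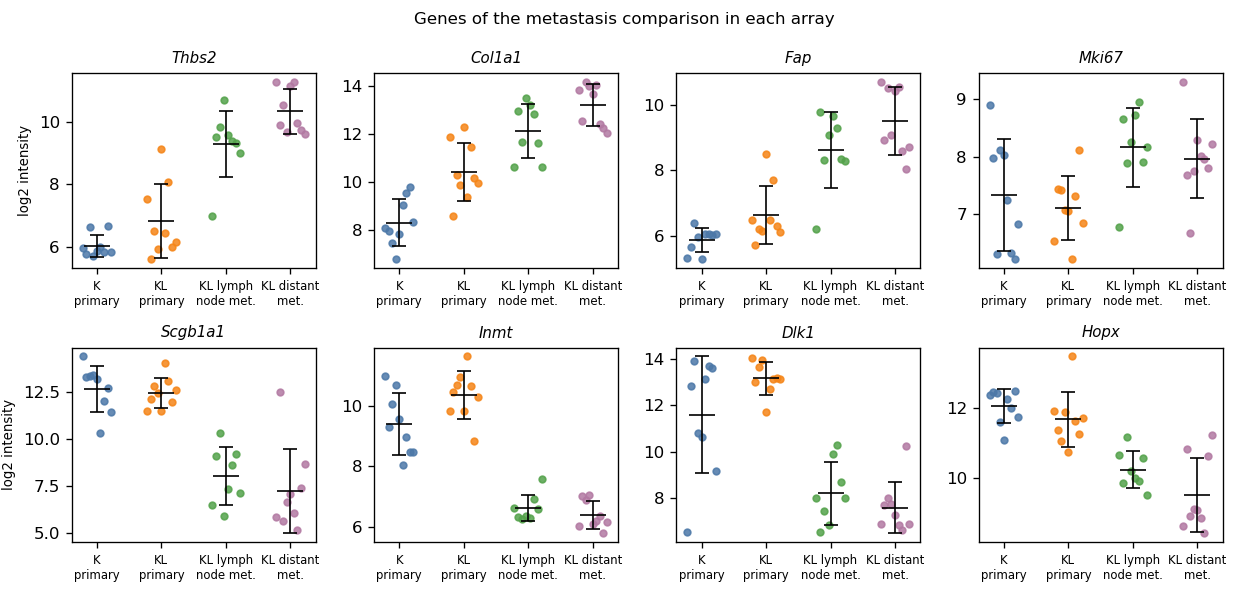
Log2 intensity (y axis) of 8 genes in every array, by group (x axis), with the group mean and SD as bars. From KL primaries to all metastases the mean of Thbs2 goes from 6.83 to 9.85, of Col1a1 from 10.44 to 12.71, of Scgb1a1 from 12.46 to 7.58 and of Dlk1 from 13.18 to 7.87.

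Of 22 collagen and matrix genes 14 rose in metastases, 0 fell and 8 did not pass (median 1.33, adjusted p = 2.41e-09), and 16 were higher and 1 lower when adjusted over the list alone. Timp1, an inhibitor of matrix proteases (2.29 ± 0.30), Col1a1, the main chain of collagen I (2.21 ± 0.35), and Col12a1 (1.69 ± 0.24) were among them. Mesenchymal transition genes had 12 of 21 higher, 0 lower and 9 not past, 14 when adjusted over the list alone (median 0.81, adjusted p = 1.07e-07). Tnc, Twist1, a transcription factor of mesenchyme (1.31 ± 0.27), and Itga5, the fibronectin receptor chain (1.18 ± 0.23), were among these. Fibroblast markers had 10 of 16 higher and 5 not past (median 1.43, adjusted p = 9.06e-06), 11 higher when adjusted over the list alone, with Fap and Thy1, a stromal surface protein (2.33). The 1 lower fibroblast marker in both counts was Tcf21, a transcription factor of lung mesenchyme (-1.30 ± 0.19). Smooth muscle markers had 4 of 10 higher and 6 not past, 5 when adjusted over the list alone (median 0.45, adjusted p = 0.00122), with Actg2 (1.24) and Acta2 (1.21), contractile actins. Cell cycle genes had 12 of 23 higher, 0 lower and 11 not past, 18 when adjusted over the list alone (median 0.48, adjusted p = 2.41e-09). They held Birc5, survivin (1.0 ± 0.17), Mki67, the proliferation marker (0.78 ± 0.16), and Mcm5, a replication helicase subunit (0.73 ± 0.15). With an estimated correlation each of these 5 lists had an adjusted p of 0.188.

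Normal lung groups were lower. Alveolar type 2 genes had 9 of 17 lower, 0 higher and 8 not past, 15 lower when adjusted over the list alone (median -1.64, adjusted p = 1.99e-08, 0.298 with an estimated correlation). They included Hc, a complement gene expressed in these cells (-2.94 ± 0.60), Etv5 (-1.47 ± 0.31) and Abca3, the lipid transporter of surfactant (-1.30 ± 0.32). Club cell markers had 5 of 10 lower and 5 not past, 6 when adjusted over the list alone (median -1.44, adjusted p = 8.54e-06, 0.110 with an estimated correlation). Alveolar type 1 markers had 4 of 9 lower and 5 not past, 5 when adjusted over the list alone (median -0.96, adjusted p = 0.00122, 0.188 with an estimated correlation), with Hopx (-1.64 ± 0.35) and Ager (-2.19 ± 0.61). Endothelial markers, unlike the fibroblast ones, had 6 of 16 lower, 0 higher and 10 not past, 7 when adjusted over the list alone (median -0.53, adjusted p = 1.99e-06, 0.188 with an estimated correlation), with Vwf (-1.84 ± 0.21) and Esam (-1.27 ± 0.13). In 3 distant metastases, KL metastasis 7, 8 and 14, the alveolar type 2 score was -4.04, -3.44 and -3.43, against -2.14 to 0.89 in the other 14.

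Smaller shifts were seen in other lists. Metastasis-associated genes had 6 of 19 higher, 0 lower and 13 not past, 6 when adjusted over the list alone (median 0.21, adjusted p = 0.0129, 0.188 with an estimated correlation). They held Mmp13, Mmp9, a gelatinase (2.04), and Mmp14, a membrane-bound metalloprotease (1.62). Src and focal adhesion genes had 4 of 21 higher and 17 not past, 4 when adjusted over the list alone (median 0.20, adjusted p = 0.00951, 0.453 with an estimated correlation), Itgb5 among them (0.60). Macrophage markers had 5 of 17 higher, 1 lower and 11 not past, 8 and 1 when adjusted over the list alone (median 0.33, adjusted p = 0.0104, 0.531 with an estimated correlation). Csf1r, the receptor for the macrophage growth factor, rose (1.14), while Chil3, a chitinase-like protein of alveolar macrophages, fell (-2.48). Cytokines had 4 of 19 higher and 15 not past, 5 when adjusted over the list alone (median 0.20, adjusted p = 0.00669, 0.335 with an estimated correlation). Squamous genes had 3 of 19 higher and 16 not past, 3 when adjusted over the list alone (median 0.17, adjusted p = 0.0453, 0.345 with an estimated correlation), Krt14, a basal keratin (2.09), among them. ERK output genes had 5 of 15 lower and 10 not past, 6 when adjusted over the list alone (median -0.27, adjusted p = 0.00936, 0.188 with an estimated correlation). Lower members were Spry2, a feedback inhibitor (-0.92), and Etv5, which is also on the alveolar type 2 list. Sterol and fatty acid synthesis genes had 3 of 17 lower and 14 not past, 8 when adjusted over the list alone (median -0.24, adjusted p = 0.0006, 0.110 with an estimated correlation). Acly, which makes acetyl-CoA in the cytosol (-0.45), was 1 of them. Hypoxia and glycolysis genes had 3 of 19 lower, 1 higher and 15 not past, 5 and 1 when adjusted over the list alone (median -0.21, adjusted p = 0.00951, 0.484 with an estimated correlation). Bnip3, a mitophagy receptor (-0.93), was lower and Ddit4, an mTORC1 inhibitor (0.47), higher. Oxidative phosphorylation genes had 4 of 25 lower and 21 not past, 4 when adjusted over the list alone (median -0.08, adjusted p = 0.0129, 0.542 with an estimated correlation), Cox7a2 among them (-0.29). Of the LKB1 pathway members 3 of 16 were lower and 13 not past, 3 when adjusted over the list alone, and the list did not pass (adjusted p = 0.191).

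Epithelial junction and keratin genes had 1 of 24 higher, 0 lower and 23 not past, 1 when adjusted over the list alone, yet the list lay lower (median -0.34, adjusted p = 0.0337, 0.635 with an estimated correlation). The higher member was Cldn4, a tight junction claudin (1.05 ± 0.25). Without the 2 rib cage metastases and the primary of stem L861 the median was -0.03 and the list did not pass (adjusted p = 0.705), nor did it without the array labelled KL metastasis 1 (0.110) or KL metastasis 7 (0.142), 8 (0.0648) or 16 (0.0511). The plot of epithelial against mesenchymal scores shows these 2 metastases, KL metastasis 7 and 8, apart from all other arrays. B cell markers (0 of 14 called, also when adjusted over the list alone, median 0.29, adjusted p = 0.0404, 0.570 with an estimated correlation) and skeletal muscle markers (0 of 18, also over the list alone, median 0.40, adjusted p = 0.0453, 0.641 with an estimated correlation) passed as lists without any gene called. Neither list passed without the array labelled KL metastasis 1 (adjusted p = 0.0970 and 0.161). The B cell list also failed to pass without L1058 (0.107), L861 (0.0658) or any of KL metastasis 3, 4, 8, 13 and 17 (up to 0.0824), and the muscle list without KL metastasis 7, 12 or 15 (up to 0.0594). Without KL metastasis 2, a rib cage metastasis with a skeletal muscle score of 3.80, the muscle median was 0.13 (adjusted p = 0.0751).

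**Figure D4:**
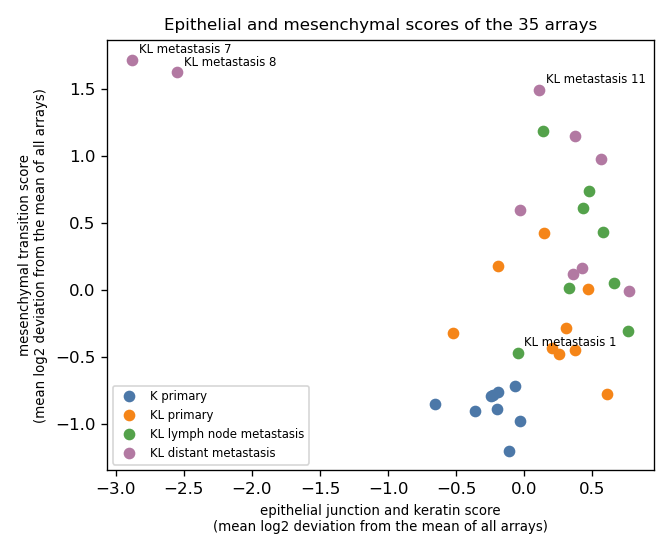
Mean epithelial junction and keratin score (x axis) against mean mesenchymal transition score (y axis) of the 35 arrays, both as log2 deviations from the mean of all arrays, coloured by group. KL metastasis 7 and 8 sit at epithelial scores of -2.88 and -2.55 and mesenchymal scores of 1.72 and 1.62, and the other 33 arrays lie at epithelial scores between -0.66 and 0.77.

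Without the array labelled KL metastasis 1 and KL metastasis 7, 8 and 14, the arrays that stood apart, 2002 genes passed (1037 higher, 965 lower), and with the 3' to 5' difference as a covariate 1039 passed. Lymph node metastases alone gave 610 genes and distant metastases alone 789. With the uninvolved lung score as a covariate, the mean of alveolar type 1, endothelial and club markers, 60 genes passed, the matrix median was 0.64 (adjusted p = 0.000954) and the alveolar type 2 median was 0.73, with its sign turned. Metastasis against primary explained 70.5% of that score's variation within stems. Leaving out stem L935, L861 or L1057 gave 688, 1125 and 1139 genes. Without L935 the calls of Lum (adjusted p = 0.0624), Cldn4 (0.0732), Itgb5 (0.0809), Acly (0.0700), Cox7a2 (0.0736) and Ddit4 (0.175) ended. The calls of Sftpa1 and Ager ended without L935 (0.103 and 0.0967), L861 (0.110 and 0.0814), L1057 (0.0611 and 0.0545) or L1058 (0.0689 and 0.0523). The call of Itgb5 also ended without L861 (0.0569), and that of Ddit4 without L861, L987, L1057 or L1058 (up to 0.0723). The Src and focal adhesion list did not pass without L935 (adjusted p = 0.0602), and the squamous, hypoxia and oxidative phosphorylation lists did not pass without the array labelled KL metastasis 1 (adjusted p = 0.295, 0.0970 and 0.184). The squamous list also did not pass without L935 (0.0724), L951 (0.0615), KL metastasis 3 (0.0530), 14 (0.0715) or 15 (0.0506), nor the oxidative phosphorylation list without L935 (0.0724). The 1 other probe set of Itga5, Acta2 and Spry2, 3 of the 4 others of Acly and 1 of the 2 others of Fmo2 did not pass.

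KL metastases were also set against K primaries, as the third pair of the 3 groups, with the metastases averaged per stem (8 values against 9). Stk11 fell by 0.99 ± 0.21 (log2, SE, adjusted p = 0.00261). Mcpt1 rose 77.4-fold (6.27 ± 0.72), Dmbt1 63.1-fold (5.98 ± 0.72), Col1a1 18.4-fold (SE 0.46), Msln 16.6-fold (4.06 ± 0.44) and Mcpt8, a basophil protease, 16.2-fold (4.02 ± 0.46). The largest falls were in Scgb1a1 (-4.81 ± 0.70), Car8, a carbonic anhydrase relative (-4.61 ± 0.28), Bex4 (-4.49 ± 0.41), Chil1 (-4.37 ± 0.42) and Dpp4, a membrane dipeptidase (-4.34 ± 0.26). Hmga2 rose by 3.59 ± 0.37, Lox by 2.31 ± 0.46 and Vegfc by 1.02 ± 0.16, and Nkx2-1 fell by 1.36 ± 0.44 (adjusted p = 0.0433), a call that ended in 14 of the 34 fits that left out 1 array or stem (adjusted p up to 0.0795). Cd24a (0.78, adjusted p = 0.125) and Src (0.29, 0.411) did not pass. In limma 1906 genes passed, 1005 higher and 901 lower in metastases, 757 of them by a log2 of at least 1 (445 higher, 312 lower).

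Metastasis-associated genes of other tumours had 8 of 19 higher, 1 lower and 10 not past, 11 and 1 when adjusted over the list alone (median 0.78, adjusted p = 7.47e-05), and this was the only list of this comparison to hold with an estimated correlation (adjusted p = 0.0438). Collagen and matrix genes had 16 of 22 higher and 6 not past, 18 when adjusted over the list alone (median 1.75, adjusted p = 1.16e-17, 0.0884 with an estimated correlation). Mesenchymal genes had 14 of 21 higher and 7 not past, 15 over the list alone (median 1.18, adjusted p = 4.73e-12, 0.0884). Fibroblast markers had 11 of 16 higher and 5 not past, 12 and 1 lower over the list alone (median 1.94, adjusted p = 1.07e-10, 0.0818). Col3a1 (3.82 ± 0.39), Timp1 (3.51 ± 0.34) and Mmp2 (3.87 ± 0.47) were among the matrix and mesenchymal genes that rose. Src and focal adhesion genes had 8 of 21 higher and 13 not past, 12 over the list alone (median 0.49, adjusted p = 4.55e-07, 0.0884 with an estimated correlation). Itgb4 (2.62 ± 0.42) and Ptk2b (1.04 ± 0.14) were among them. Gastric genes had 6 of 17 higher, 1 lower and 10 not past, 8 and 1 over the list alone (median 0.56, adjusted p = 0.000165, 0.208 with an estimated correlation). Tff1 (2.76 ± 0.47) and Gkn1 (2.48 ± 0.43) rose. CREB and CRTC targets had 3 of 14 higher and 11 not past, 3 over the list alone (median 0.25, adjusted p = 0.0247, 0.0884 with an estimated correlation), with Sik1 (1.49 ± 0.24). Of the LKB1 pathway members 2 of 16 were higher, 1 lower and 13 not past, the same numbers over the list alone, and the list did not pass (adjusted p = 0.286).

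Alveolar type 2 genes had 9 of 17 lower and 8 not past in metastases, 14 over the list alone (median -1.51, adjusted p = 1.76e-08, 0.218 with an estimated correlation), with Hc (-3.29 ± 0.48) and Etv5 (-1.70 ± 0.38). Club markers had 6 of 10 lower and 4 not past, 6 over the list alone (median -1.69, adjusted p = 0.000703, 0.218). Alveolar type 1 markers had 4 of 9 lower and 5 not past, 4 over the list alone (median -0.89, adjusted p = 0.00843, 0.208). MHC class II genes had 3 of 9 lower and 6 not past, 3 over the list alone (median -0.36, adjusted p = 0.0247, 0.314 with an estimated correlation), H2-Eb1 among them (-2.96). Cytokines had 6 of 19 higher and 13 not past, 7 over the list alone (median 0.36, adjusted p = 0.0018, 0.218 with an estimated correlation). They held Il33, an alarmin (1.98 ± 0.31), and Il6 (0.81 ± 0.21). Mesothelial markers had 3 of 8 higher and 5 not past, 5 over the list alone (median 1.12, adjusted p = 0.00105, 0.0818). Smooth muscle markers had 3 of 10 higher and 7 not past, 6 over the list alone (median 0.56, adjusted p = 0.00129, 0.0915). Neutrophil markers had 3 of 11 higher and 8 not past, 3 over the list alone (median 0.30, adjusted p = 0.0247, 0.314), and squamous genes 3 of 19 higher and 16 not past, 3 over the list alone (median 0.06, adjusted p = 0.0247, 0.314). Skeletal muscle markers had 1 of 18 higher and 17 not past, 0 over the list alone (median 0.28, adjusted p = 0.0247, 0.651). The last value in each of these parentheses is the adjusted p with an estimated correlation. Without the array labelled KL metastasis 1 the neutrophil (adjusted p = 0.0786), squamous (0.299) and skeletal muscle (0.105) lists did not pass, and without stem L861 the MHC class II list did not (0.0535). Without KL metastasis 2 the skeletal muscle list did not pass (0.379). Epithelial genes had 3 of 24 higher and 21 not past, 2 over the list alone, with Krt19 (1.30) and Cldn4 (1.53) among them, and the list did not pass (adjusted p = 0.403).

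With code range as a block 1728 genes passed in this comparison, 1425 above 600 (7 stems against 4 arrays) and 190 below it (1 stem against 5). The 1 stem below 600 was L592, so its value rests on a single metastasis assumed to vary like the others. Stk11 was -1.21, -1.22 and -1.18 in these settings (adjusted p = 0.337 below 600), Col1a1 3.72, 3.33 and 4.93, Hmga2 3.94, 4.01 and 3.73 and Scgb1a1 -3.58, -4.41 and -1.04 (0.437 below 600). The fall of H2-Eb1 was -1.31 above 600, where it did not pass (0.0522). Krt19 did not pass with the block (0.102) or above 600 (0.257), nor without any of 5 stems or 2 K primaries (up to 0.0669). The median of the matrix list was 1.80, 1.85 and 1.84 and of the metastasis-associated list 1.05, 0.97 and 0.94. Without the array labelled KL metastasis 1 and KL metastasis 7, 8 and 14 the count was 2676 (1497 higher, 1179 lower).

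The last comparison set 8 lymph node against 9 distant metastases with code stem as a block, to ask whether the site changed expression. With that block only the 4 stems that held both kinds, L935, L951, L987 and L1057, inform the difference. Stk11 differed by -0.08 ± 0.15 (log2, SE, adjusted p = 1). In limma 0 genes passed, and 379 had an unadjusted p under 0.05. The gene nearest to the threshold among those named was Actg2, a smooth muscle actin, lower by -1.39 ± 0.17 in lymph node metastases (adjusted p = 0.130), followed by Tnc (-2.23 ± 0.33, 0.327). Lymphocyte genes lay higher in lymph node metastases without passing singly, such as Jchain, the joining chain of secreted antibodies (3.66 ± 1.07), and Ighm, the heavy chain of IgM (2.80 ± 0.87), both at an adjusted p of 1. Hmga2 (0.58), Nkx2-1 (0.56), Vegfc (0.24), Src (0.00), Cd24a (-0.08) and Lox (-0.75) had adjusted p values of 1.

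Camera passed 17 lists here, of which 0 held with an estimated correlation and 0 in fry, and none of their members was called over all genes. B cell markers lay higher in lymph node metastases (median 0.62, adjusted p = 5.20e-15, 0.181 with an estimated correlation, 5 of 14 higher when adjusted over the list alone), as did T cell (0.28, 1.27e-10, 0.181, 0 of 14) and plasma cell markers (0.16, 0.00834, 0.181, 1 of 7), in the same order of values. Lymph node stroma (0.20, 0.0142, 0.181, 0 of 7) and MHC class II genes (0.20, 0.0196, 0.576, 0 of 9) followed. Collagen and matrix genes lay lower (-0.54, 1.62e-12, 0.181, 7 of 22), with mesenchymal genes (-0.38, 9.99e-06, 0.462, 1 of 21), fibroblast (-0.40, 9.68e-05, 0.462, 0 of 16), smooth muscle (-0.26, 0.000221, 0.208, 2 of 10), skeletal muscle (-0.55, 9.99e-06, 0.564, 0 of 18), macrophage (-0.36, 9.99e-06, 0.462, 0 of 17) and neutrophil markers (-0.19, 0.0220, 0.564, 0 of 11). Alveolar type 2 (1.03, 5.17e-07, 0.462, 0 of 17), club (0.71, 0.000595, 0.181, 3 of 10) and alveolar type 1 genes (0.36, 0.0455, 0.535, 0 of 9), ERK output (0.15, 0.000152, 0.181, 1 of 15) and epithelial genes (0.09, 0.0196, 0.598, 0 of 24) lay higher. Src and focal adhesion (0.01, adjusted p = 0.173), LKB1 pathway (0.06, 0.143) and metastasis-associated genes (median -0.04 with the test pointing higher, 0.928) did not pass. With the B and T cell score as a covariate 9 lists passed and the MHC class II median was -0.47. The T cell median was 0.01 in that fit, which follows from the score being made of these markers. Without KL metastasis 2 the skeletal muscle median was 0.01 (adjusted p = 0.948). Without stem L935 the mesenchymal (adjusted p = 0.130), fibroblast (0.0963), macrophage (0.424), neutrophil (0.344) and epithelial (0.316) lists did not pass, and without L951 the club list did not (0.125). The plasma cell (0.0811), MHC class II (0.0882) and alveolar type 1 (0.145) lists did not pass without L1057, and the lymph node stroma list did not without L987 (0.0552). The epithelial (0.450) and fibroblast (0.0552) lists also did not pass without L987, nor the neutrophil list (0.125), MHC class II list (0.622) and alveolar type 1 list (0.514) without L951. Without the array labelled KL metastasis 1 and KL metastasis 7, 8 and 14 the count was again 0. Of these only KL metastasis 14 belongs to a stem with both kinds of site, so that fit is a weak check.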

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

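The tests of a lower tumour share and of the distant sites on matrix genes, and all tests on the lung genes and on stem L861, were chosen after the results were seen. The matrix tests of RNA degradation and of the 4 arrays that stood apart were added after the data were seen, before their own results. The counts of other splits were planned. A sample was set apart where its gap to the nearest other was a large share of its group's range. Chance does this in about 1 in 20 groups, or 5%, and it happened in 58 of 458 groups of values (12.7%). Those groups were limited to comparisons that name the gene or list after a wider search had been counted, which gave 83 of 580 (14.3%).

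Matrix genes were higher in KL metastases than in KL primaries (median 1.33). A lower share of tumour cells with more of every other cell type would raise fibroblast and endothelial markers alike. The fibroblast score rose by 1.66 more than the endothelial score over the 8 stems (exact sign-flip p = 0.00781). Endothelial markers are also part of the uninvolved lung score, and their mean score fell from 0.38 in KL primaries to -0.13 in metastases. A lower tumour share together with less lung tissue therefore stays open. RNA degradation is argued against by a median of 1.12 with the 3' to 5' difference in the model (adjusted p = 9.52e-09), and the 4 arrays that stood apart by a median of 1.31 without them (1.70e-09). Connective tissue of distant sites alone is argued against by 1.01 with lymph node metastases only (1.76e-06), though with an estimated correlation the list did not pass before any of these changes (adjusted p = 0.188). With the uninvolved lung score in the model the matrix median was 0.64 (camera adjusted p = 0.000954), and Col1a1 did not pass (limma adjusted p = 0.306). Metastasis against primary explained 70.5% of that score's variation within stems, so this fit cannot decide whether differing lung tissue plays a part. More fibroblasts, or more matrix made by the same cells, may also underlie the pattern, and they were not tested against each other.

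Alveolar type 2, type 1 and club genes were lower in KL metastases than in KL primaries (type 2 median -1.64). RNA degradation as the whole cause is argued against by a median of -1.39 with the 3' to 5' difference in the model (adjusted p = 2.92e-07), though with an estimated correlation the list did not pass before this change (adjusted p = 0.298). Uninvolved lung tissue in the primary pieces and a change in the tumour cells cannot be told apart: with an uninvolved lung score in the model the median was 0.732, but metastasis against primary explained 0.705 of that score's variation within stems. KL metastasis 7, 8 and 14 had the lowest type 2 scores, and whether less lung tissue in these pieces could account for that cannot be told apart, since only KL metastasis 11 had as low a club score (-2.20), with a type 2 score of -2.14. No test here separates the tissue from the tumour cells.

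Epithelial genes were low in both rib cage metastases of stem L861, KL metastasis 7 and 8 (Epcam 5.78 and 6.24, Cdh1 6.16 and 6.40, against an Epcam of 11.4 in the primary of that stem). Keratins differed less from that primary: Krt8 was 10.5 and 11.3 against 12.4, and Krt18 was 8.91 and 10.9 against 10.9. Hmga2 was 11.4 and 11.2 against 9.03. Why these genes differed unevenly was not tested. RNA degradation is argued against by the 3 other arrays with a 3' to 5' difference above 1, of which the lowest epithelial score was -0.0289. The mean Stk11 of the pair was 7.14, below the midpoint of 7.99 between K and KL primaries, but Stk11 also fell with the 3' to 5' difference among K primaries (r = -0.80, exact permutation p = 0.00649, n = 9), and both arrays lie beyond those, so few tumour cells stay open. The lower mesenchymal score of the pair was 1.62, above the highest other metastasis at 1.49, but the fibroblast scores were 1.94 and 1.49, with B cell (1.17), macrophage (0.75) and neutrophil (1.71) scores in KL metastasis 8. A tumour that lost epithelial genes and a piece rich in stroma cannot be told apart.

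KL primary 5, of which the 3' to 5' difference was 1.41 (mean of the others 0.358), stood apart in 16 measures. Its alveolar type 2 score was -0.611, alveolar type 1 score -0.434, Sftpa1 12.01, Ager 8.61, Etv5 7.39, Nkx2-1 5.70 and Esam 9.56, all below the other KL primaries. Its Tnc (10.5), Fbn2 (7.98), Sfrp2 (8.21), Twist1 (6.15), Ddc (6.36), Pf4 (8.22), Cltrn (4.39) and cytokine score (0.409) lay above.

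The array labelled KL metastasis 1 stood apart in 14 measures among lymph node metastases. Its Stk11 (8.47), Bex4 (5.79), Tcf21 (7.17) and skeletal muscle score (0.723) lay above the others. Its Thbs2 (6.997), Fap (6.22), Src (8.47), Krt14 (8.64), Acta2 (8.90), Ptk2b (8.33), Ddit4 (9.34), Src and focal adhesion score (-0.379), oxidative phosphorylation score (-0.401) and median of all genes (7.40) lay below. Its Slc2a3 of 4.91 was below every K primary. Its second Stk11 probe set, at 7.67, was above every K primary (highest 7.15). That probe set did not separate the groups, so its value does not tell whether Stk11 was at the K level. Its intensities were the most compressed of the 35 arrays (25th percentile 65.5, 75th percentile 302), and its highest correlation with any other array was the lowest of the 35 (0.887). Array quality, a wrong label, a mixed piece and a tumour with the gene left in part were not tested against each other.

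KL metastasis 14 had a hypoxia score of 0.619, a CREB and CRTC score of -0.512, H2-Eb1 of 6.97 and Tgfbi of 9.09. K primary 4 had Dmbt1 of 8.65, Msln of 8.38 and Mcpt8 of 8.14 above the other K primaries and Plagl1 of 8.18 below them. KL primary 6 had a Src and focal adhesion score of -0.466, Car3 of 6.27 and Hopx of 13.5. KL metastasis 17 had a gastric score of 1.99, Tff2 of 13.6 and Bnip3 of 10.9. KL metastasis 15 had Dlk1 of 10.2 and Chil1 of 10.4, and KL metastasis 6 a club score of 1.28 and Scgb1a1 of 12.5. KL primary 1 had an ERK output score of 0.560 and Mmp9 of 9.65, and K primary 3 Prap1 of 7.11 and Mark4 of 8.02. KL metastasis 8 had a plasma cell score of 0.813 and KL metastasis 2 a skeletal muscle score of 3.80. K primary 9 had Chil1 of 9.92, K primary 6 Hc of 9.00, KL primary 4 Col12a1 of 7.22 and KL primary 8 Mcm5 of 7.36. No explanation of these was tested.

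Other splits of the same arrays were counted for each comparison, the real one included. For KL against K primaries 1 of 100 splits gave as many as the real 1333 genes, and the highest other gave 470. For metastases against KL primaries, split within stems, 1 of 100 gave as many as 1719, and the highest other gave 1. For metastases against K primaries 1 of 100 gave as many as 1906, and the highest other gave 2. A chance division of the arrays is argued against for these 3, as far as 100 splits can tell. The splits for KL against K primaries did not hold code range or stem fixed. Those for metastases against K primaries did not hold code range fixed either, so neither set speaks to a possible batch. For lymph node against distant metastases, with 0 genes by limma and 379 at an unadjusted p under 0.05, all 72 splits had to give as many, so their count says nothing about chance (highest other 4).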

How the results depend on the processing

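The settings with code range, with the 3' to 5' difference, without the 4 arrays that stood apart, and without single metastasis arrays were chosen after the data were seen, and the others were planned. Settings that leave out 1 array or stem are not counted here. Direction was compared only where a value passed in the main or the other fit. On that rule named genes kept direction and side of the threshold in 933 of 1005 values for KL against K primaries and 1778 of 2090 for metastases against KL primaries. They did so in 1291 of 1404 for metastases against K primaries and 1238 of 1242 for lymph node against distant metastases. In that last comparison 0 genes passed in the main fit, so its count says little about direction. Lists did so in 499 of 531, 545 of 642, 514 values (41 others no longer passed, 12 newly passed and 1 reversed) and 383 of 463.

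For KL against K primaries the 1333 genes became 2039 probe sets with every probe set tested, 3627 with array weights, 2285 with code range as a block, 3823 above 600 and 142 below it, where fewer arrays were left. For metastases against KL primaries the 1719 became 3391 with array weights, 1039 with the 3' to 5' difference, 1078 with no stem block, 878 with 8 pairs of stem means, 610 with lymph node and 789 with distant metastases alone, and 60 with the uninvolved lung score. In that last setting the median standard error rose from 0.110 to 0.195, and 86.2% of called genes kept their sign. For metastases against K primaries the 1906 became 5881 with array weights, 2889 with all 35 arrays in 1 fit, 3429 with the 17 metastases as separate arrays and 190 below 600. For lymph node against distant metastases the count of 0 in limma (379 at unadjusted p under 0.05) became 1 with array weights, 15 with all arrays in 1 fit and 4 with stem as a random block. Beyond the smaller numbers of arrays, the cause was not tested.

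With the title number as a block, 1087 genes and 11 lists passed for KL against K primaries, and 880 genes and 20 lists for metastases against KL primaries. Paired by title number, arrays did not deviate together (median r -0.06 and 0.06), while KL primaries and metastases of 1 stem did (median r 0.31 over 18 pairs, against -0.02 for other pairs).

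With an estimated correlation 1, 0, 1 and 0 lists passed in the 4 comparisons, in the order above, against 11, 21, 17 and 17 with the preset one. Fry passed 10, 15, 18 and 0 lists in the same order. The B and T cell score as a covariate left 9 lists for lymph node against distant metastases. For metastases against KL primaries 11 lists passed with the uninvolved lung score and 13 without the 4 arrays that stood apart. The estimated correlation widens the test where list members vary together, and for the others the cause was not tested.

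Some directions reversed. With the uninvolved lung score, metastases against KL primaries gave Sftpa1 1.84, Itih4 0.93, Hc 0.29, Etv5 0.0063, Abca3 0.21, Scgb3a1 0.11, Hopx 0.083 and Ager 1.22, and medians of 0.73 for alveolar type 2, 0.15 for alveolar type 1 and 0.75 for MHC class II genes. None of these genes passed in that fit, nor did the alveolar type 1 list (camera adjusted p = 0.834). The score itself holds the alveolar type 1 and club markers, Hopx, Ager and Scgb3a1 among them, so their values follow in part from construction. For lymph node against distant metastases MHC class II stood at -0.47 with the B and T cell score, at -0.14 without stem L951 and at -0.14 without KL metastasis 13 (0.54 at the highest, without L935). Cell cycle genes stood there at -0.20 without stem L935 (0.19 at the highest, without L1057), at 0.095 above code 600 for KL against K primaries, and at -0.51 below 600 for metastases against K primaries. Below 600 Cldn7 was at -0.066 for KL against K primaries and Scgb3a1 at 0.71 for metastases against K primaries.

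For other lists the direction of the test turned while the median kept its sign. For metastases against KL primaries these were B cell markers at 0.034 with the B and T cell score and 0.024 with distant metastases alone, cytokines at 9.54e-05 with the uninvolved lung score, and skeletal muscle at 0.0083 with its own score, which removes it by construction. The B and T cell score likewise removes B and T cell markers by construction. The epithelial list there was at -0.025 with lymph node metastases alone, -0.022 without the 4 arrays and -0.026 without stem L861. For lymph node against distant metastases these were interferon genes at -0.24 and T cell markers at 0.0074 with the B and T cell score, and gastric genes at -0.28 with the 3' to 5' difference. Where no construction explains it, the cause was not tested.

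Leaving out 1 array or stem gave 928 to 1491 genes and 11 to 13 lists for KL against K primaries, 688 to 2161 and 15 to 23 for metastases against KL primaries, 1493 to 2580 and 14 to 18 for metastases against K primaries, and 0 to 1 and 13 to 19 for lymph node against distant metastases. The 688 came without stem L935. For lymph node against distant metastases, arrays of stems that did not hold both kinds of site could not change the log2 differences. Without the dimmest 30% of genes, where signal is nearest to background, 1242, 1651, 1766 and 0 genes passed in the 4 comparisons.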

Other observations

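The tests relating Nkx2-1 to other genes were chosen after the result was seen, and the others in this part were added after the data were seen, before their own results. Hmga2 was higher where Nkx2-1 was lower across the metastases. Over the means of 8 stems Pearson's r was -0.849 (exact permutation p = 0.00873, adjusted p = 0.0262 over 3 relations), Spearman's rho was -0.64 (p = 0.0962, adjusted p = 0.198), and r was -0.73 without L1044 and L861, the 2 stems farthest from the median of Nkx2-1. This may be a link between loss of lung identity and Hmga2, as a hypothesis that rank correlation did not carry past the threshold. Stem L1044 holds the array labelled KL metastasis 1 alone. For the alveolar type 2 genes r was 0.736 (p = 0.0794, adjusted p = 0.119; rho 0.595, p = 0.132, adjusted p = 0.198) and -0.08 without these 2 stems, so no relation could be told. For the gastric genes r was 0.42 (p = 0.276, adjusted p = 0.276, rho 0.381 with p = 0.360) and 0.04 without the 2 stems. Neither value was below 0, but 8 stem means are too few to tell whether these genes go against Nkx2-1.

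Taken over all genes, the difference between metastases and primaries did not continue the genotype difference as a general pattern. With the KL primaries of 4 stems in one comparison and those of the other 4 in the next, the covariance of the log2 differences was above 0 in 52.9% of 70 such divisions (median covariance 0.000569, r between -0.20 and 0.21). These divisions share stems. Of 270 genes called in both comparisons 80 were higher in both, 73 lower in both, 99 higher and then lower and 18 lower and then higher, against 46.0, 45.2, 57.5 and 36.2 if the calls were independent. Both comparisons share the KL primaries, which by itself favours opposite directions. Hmga2 was among the genes higher in both. Single lists could still continue. The matrix, mesenchymal, fibroblast, Src and focal adhesion, and metastasis-associated lists passed preset camera as higher in both comparisons. The endothelial and epithelial lists passed as higher and then lower, and the cell cycle list as lower and then higher. None of them held for metastases against KL primaries with an estimated correlation.

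More mast cells were tested as the source of the high Mcpt1 and Mcpt8 in KL tumours. The other 11 mast cell genes had a median of -0.106 for KL against K primaries, with 4 of 11 above 0, which argues against a rise of the whole set. Mcpt2 (2.87) and Kit (1.32) were higher and Hdc (-1.16) lower. More mast cells of a kind that carries only some of these genes was not tested. Their median was 0.21 for metastases against KL primaries and -0.03 for metastases against K primaries.

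A joint fall of imprinted growth genes was tested because Dlk1 fell in metastases and Plagl1 in KL primaries. The other 11 such genes had a median of -0.0737 for metastases against KL primaries, with 7 of 11 below 0, which argues against a fall of the whole set. Meg3 (-1.91) and Slc38a4 (-2.34) fell with Dlk1. The median was 0.33 for KL against K primaries, where Slc38a4 rose by 2.63, and 0.30 for metastases against K primaries.

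The most alike arrays were KL metastasis 10 and 12, both of stem L935, with r = 0.996 over all genes and 34 genes that differed by a log2 of at least 1. All arrays of a stem had the same class of Eif2s3y, a gene of the Y chromosome, in 8 of 8 stems.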
